A study of Drosophila melanogaster with 2 samples.

How the data were processed

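The data were ChIP-seq peak lists from 2 biological replicates of Drosophila melanogaster embryos (0 to 16 h) of a line carrying Salm fused to GFP, precipitated with an antibody against GFP. Per the labels, chromatin was sonicated to fragments of 200 to 800 bp, and the coordinates are those of dm6. Both replicates belong to 1 group, and the labels count them as separate biological samples.

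Per the deposited descriptions, the authors called peaks on each replicate alone and on both replicates pooled, each against a control, and derived a thresholded list by the irreproducible discovery rate (IDR), a filter on the consistency of peak ranks between replicates. The control itself was not analysed here. The aligner, the peak caller, their versions and the IDR threshold are not given in the sources used here. The deposited signal of each peak is the peak caller's own strength value. Its scale differs between lists, so signals were compared within a list, and across lists only by ranks or by correlations over peaks. The deposited −log10 q-value of each peak has a ceiling in every list (4.08 in the pooled and thresholded lists), and all 3421 thresholded peaks sit at it, so it was not used to rank peaks. The 3 unthresholded lists hold exactly 30000 peaks each, so their length says nothing about how much was bound. All 3421 thresholded peaks occur unchanged in the pooled list and are its strongest 3421. In 61.4% of the thresholded peaks the summit is the middle of the peak, and 60.8% have a width of 390 bp, which limits how finely a summit places binding.

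Read totals were not given, so no depth per sample can be stated. Intervals on shares of peaks are exact (Clopper-Pearson) 95% binomial intervals over peaks and cover counting error only. With 1 group and 2 replicates there was no test between conditions, and p-values below compare peaks with random positions, flanks or random gene lists. They do not measure the spread between replicates.

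Genes, transcripts and exons came from Ensembl release 115 (FlyBase 6.54 annotation), and sequence from Release 6 of the genome, the assembly that dm6 names. Arms 2L, 2R, 3L, 3R, 4 and X were used. Each summit was assigned to 1 class in the order TSS within 500 bp, 5′ untranslated region, coding sequence, 3′ untranslated region, other exon, intron and intergenic, and compared with 1000 sets of random positions with as many positions per arm. A gene was called bound when a thresholded summit lay between 2 kb upstream of it and its end, so a summit in overlapping windows counted for each gene. Bound members of a list were compared with 10000 random lists of protein-coding genes matched on window length in 20 quantile bins, for lists of at least 8 annotated genes. Sequence within 50 bp of each summit was compared with a window of equal width centred 300 bp to a side drawn at random, with the exact McNemar test for words and a sign-flip permutation test for GC content. Tests are two-sided, and families were adjusted by the Benjamini-Hochberg method at 0.05. Replicate overlap was set against 1000 circular shifts within arms. The bootstrap of the correlation drew 1000 samples of peaks.

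The tests, gene lists, motifs and alternatives were fixed before the data were examined, except where the closing section says otherwise. The fixed lists were spalt genes, gap and head gap, pair-rule, segment polarity, homeotic, tracheal, EGFR pathway and oenocyte, sensory organ, neuroblast, glial, muscle, fibrillar flight muscle, Dpp pathway and wing, photoreceptor, hemocyte and fat body, germline, gut, cuticle and epidermal, cell cycle and heat shock genes, and cytosolic ribosomal protein genes by symbol. Of their 269 listed symbols, 4 were matched through synonyms and 1, dys, was left out as ambiguous. Genes are named by a fixed rule: the gene with the TSS nearest to each of the 20 strongest peaks; salm and salr; for each list up to 4 bound members with the strongest peaks and up to 2 unbound members with the longest windows; and the 5 genes with the most summits. Some genes owning the TSS nearest to a named peak, and lncRNA:CR46454, were named after their values were seen.

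Alternatives changed 1 choice at a time: the strongest 1710 thresholded peaks; the 3421 strongest peaks of a single replicate; TSS windows of 250 and 1000 bp; protein-coding transcripts only; weak peaks, GC-matched positions (bins of 2.5 percentage points) or dinucleotide shuffles as background; other gene windows; windows of 100 bp and flanks at 1000 bp; and leaving out 232 summits within 1000 bp of a stronger one. The scripts were tested on simulated data. Of 100 random lists without effect over 13945 genes, 2 had an unadjusted p under 0.05, and all 100 lists of 16 genes given a summit at 8 members were called. With all summits moved by 1000 bp, 1 of 2080 words passed, and a word planted in 200 windows ranked 1. The analysis used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.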

Results

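Chromatin immunoprecipitation followed by sequencing (ChIP-seq) was used to locate Spalt major (Salm) on the genome of Drosophila melanogaster embryos. Salm is a zinc-finger transcription factor that acts in the embryonic head and tail, the tracheal system, oenocytes and sensory organs. The embryos came from a transgenic line carrying salm fused at its C-terminal end to GFP, and an antibody against GFP pulled down the tagged protein. Whole embryos aged 0 to 16 h were used, so each value is an average over many tissues and stages. There was 1 group of 2 biological replicates and no second condition, so the questions answered here are where the tagged protein lay and how well the replicates matched. The thresholded list, which rests on both replicates, held 3421 peaks with a median width of 390 bp and a signal between 141 and 2154 in the units of the authors' peak caller. The pooled list and each replicate list held 30000 peaks. Read totals were not given in the sources used here, so the depth of each library is unknown.

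The strongest peaks of the thresholded list ranked high in both libraries. That list was drawn from both replicates pooled and filtered on consistent ranks. These ranks are therefore no independent measure of how well the libraries match. The strongest peak, at CG14100 (arm 3L, 19590448 to 19590795 in dm6, summit 87 bp upstream of the transcription start site, TSS), had a signal of 2154 and ranked 1 in each replicate. Ugalt, a UDP-galactose transporter gene, followed with a signal of 2076 (arm X, 2703709 to 2704062, summit 28 bp upstream of the TSS; ranks 2 and 4). The peak next to cbt, 1401 bp upstream of its TSS in an intron and within the window of ush, reached 2066 (arm 2L, 480893 to 481280; ranks 4 and 2). An intronic peak of CG11050 reached 2049, and an intergenic peak nearest to CG13323 reached 1979. All of the 20 strongest peaks had signals of at least 1527 and ranked 21 or better in replicate 1 and 23 or better in replicate 2.

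Of these 20 peaks, 14 had their summit within 500 bp of an annotated TSS. Beside CG14100 and Ugalt, the peaks at a TSS were those of px, CG18549, CG1635, CG11309, CenG1A, the mitochondrial ribosomal protein genes mRpS10 and mRpL41, PNPase, which encodes a polynucleotide phosphorylase, the peptidyl-prolyl isomerase gene Fkbp14, the glycolytic gene Gapdh2, and Chro and ph-p, which encode chromatin proteins. mRpS10 had a signal of 1858 (arm 3R, 15229367 to 15229694) and mRpL41 a signal of 1769 (arm 2R, 15217599 to 15217913). Gapdh2 reached 1628, Chro 1541 and ph-p 1527. An intronic peak 1535 bp downstream of a TSS of Trl, which encodes the GAGA factor, reached 1589. Non-coding genes were nearest at the peaks of lncRNA:CR44366 (signal 1927, intron) and lncRNA:CR44619 (signal 1801, exon).

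Across the whole lists, 2546 of the 3421 strongest replicate 1 peaks (74.4%, exact 95% binomial interval 72.9 to 75.9) overlapped a peak among the equally many strongest of replicate 2 by at least 1 bp. Peaks shifted around the arms overlapped in 1.67% of cases on average and in at most 2.51% over 1000 shifts. Of the thresholded summits, 3379 (98.8%, interval 98.3 to 99.1) lay inside a peak of each full replicate list, against 4.19% on average and at most 5.47% after shifting. The thresholded list consists of the strongest peaks of both replicates pooled, so this share is no independent measure of how well the libraries match. Another 20 lay in a replicate 1 peak only, 21 in a replicate 2 peak only and 1 in neither. Across 3410 thresholded peaks matched in both lists, the signals of the replicates had a Spearman rho of 0.730 (bootstrap 95% interval 0.71 to 0.75) and a Pearson r of 0.846 on the log2 scale. Over all 21180 replicate 1 peaks that overlapped a replicate 2 peak, rho was 0.605. These correlations are across peaks, which are not independent replicates. Only 72.6% of thresholded summits lay in a peak of both replicates when each replicate list was limited to its 3421 strongest peaks.

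**Figure D1:**
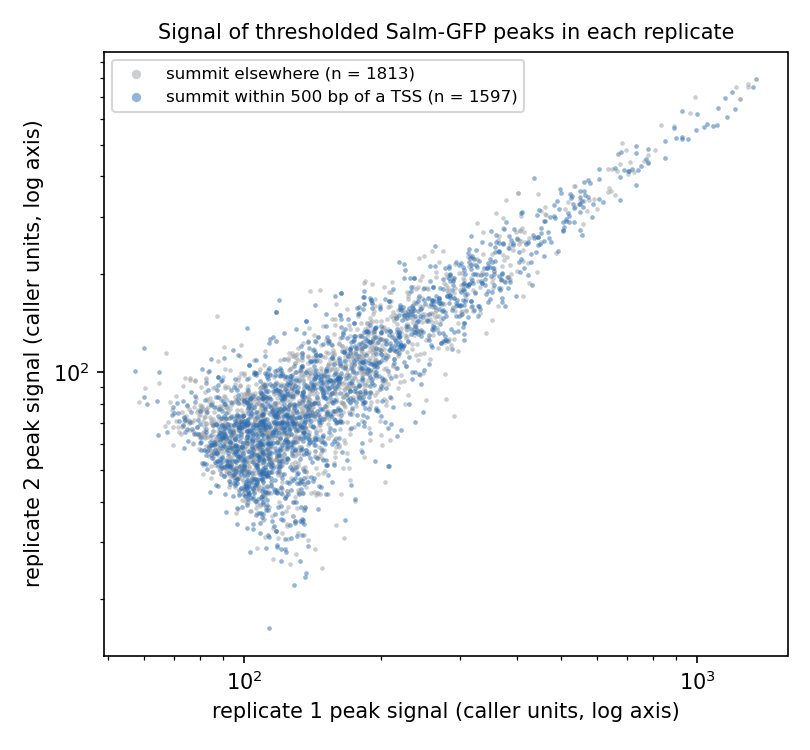
Signal of each of 3410 thresholded peaks in replicate 1 (x axis) and replicate 2 (y axis), in peak caller units on log axes, with summits within 500 bp of a TSS in blue and other summits in grey. The points lie along a diagonal (rho 0.730), and the spread is wider among weak peaks.

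The salm gene itself carried binding, and its paralogue salr did not pass the threshold. The window of salm, from 2 kb upstream of the gene to its end, held 3 thresholded summits. The strongest (signal 299, rank 880; arm 2L, 11446003 to 11446283) lay 531 bp upstream of the TSS, and the others lay in the same intron, 1258 and 4421 bp downstream, with signals of 179 and 214. The most strongly bound site nearby (signal 616, rank 199; arm 2L, 11447672 to 11447964) lay 240 bp upstream of lncRNA:CR46454, the next gene upstream of salm. Including 50 kb on either side, the salm region held 8 thresholded summits. Of 780 genes whose length was within 25% of that of salm, 70 (8.97%) had as many or more, and their median was 3. The window of salr held 0.

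**Figure D2:**
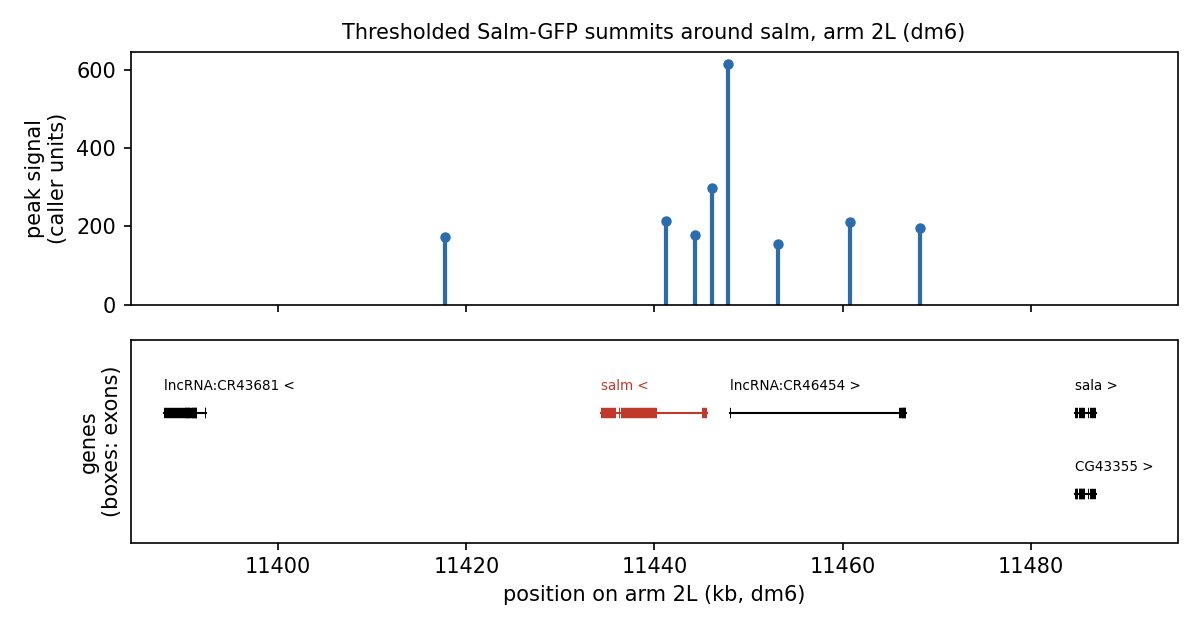
Thresholded summits within 50 kb of salm on arm 2L of dm6 (top, height is the peak signal in caller units) above the annotated genes (bottom, boxes are exons, arrows give the strand). The 8 summits have their highest point, 616, just upstream of lncRNA:CR46454.

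Binding was concentrated at gene starts and nearly absent from coding sequence over 500 bp from a TSS. Of the 3421 summits, 1605 (46.9%, exact 95% binomial interval 45.2 to 48.6) lay within 500 bp of a TSS, against 13.6% ± 0.605 (SD over 1000 sets) of random positions on the same arms. Among these, 1208 lay upstream and 393 downstream, with a median of 107 bp upstream. Any position within 500 bp of a TSS was counted there, also one in coding sequence or an untranslated region. The other classes, for summits and random positions alike, thus cover only sequence farther from a TSS. Only 4 summits (0.117%) lay in coding sequence, against 13.8% ± 0.605 of random positions, 4.82% of positions matched on GC content and 2.36% of pooled peaks outside the thresholded list, and 30 (0.877%) lay in 3′ untranslated regions, against 4.39% ± 0.361. Intergenic summits numbered 409 (12% against 27.3% ± 0.772). Introns held 1314 summits (38.4% against 39.3% ± 0.851), which did not differ from random positions (permutation test, adjusted p = 0.357), nor did 5′ untranslated regions with 23 (adjusted p = 0.579) or other exons with 36 (adjusted p = 0.235).

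The shares at gene starts, in coding sequence, in 3′ untranslated regions and between genes each had p = 0.002 (two-sided permutation test, the smallest that 1000 sets can give; Benjamini-Hochberg adjusted p = 0.0035 over 7 classes). Weak peaks, the 25837 pooled peaks that overlapped no thresholded peak, had 28.9% of their summits at a TSS. In introns the thresholded share lay below the background when tested against weak peaks (46%, Fisher's exact test, adjusted p = 7.7e-17), with random positions matched on GC content (43.5%, adjusted p = 0.0028), with the strongest 1710 peaks and without replicate 2. The share in 5′ untranslated regions (0.672%) was also below that of weak peaks (1.07%, Fisher's exact test, adjusted p = 0.0346).

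**Figure D3:**
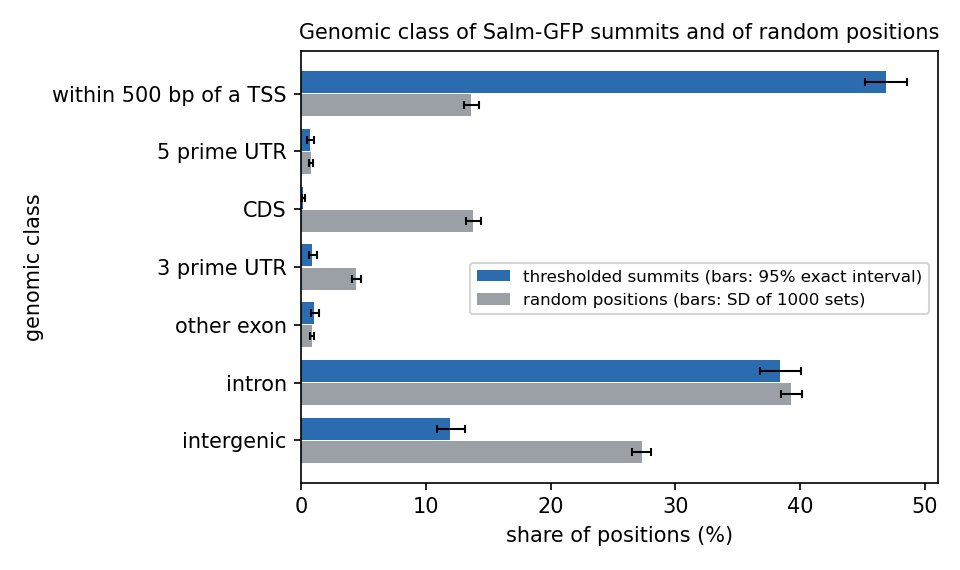
Share of the 3421 thresholded summits (blue, bars are exact 95% intervals) and of random positions (grey, bars are the SD of 1000 sets) in each genomic class, in percent, with each position counted in 1 class. Summits within 500 bp of a TSS make up 46.9% against 13.6%, and coding sequence farther from a TSS holds 0.117% against 13.8%.

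A separate group of 1023 summits (29.9%, interval 28.4 to 31.5) lay over 2 kb from any TSS. Summits within 500 bp of a TSS had a median signal of 214, against 200.2 for the other 1816 summits, a difference of 13.9 (two-sided permutation test over peaks with 100000 resamples, p = 2.7e-04). In the strongest quintile of peaks 58.1% of summits lay at a TSS (interval 54.3 to 61.8), and in each weaker quintile between 42.4 and 46.1%. Peaks are not independent replicates. The difference in medians did not pass with a TSS window of 250 bp (1.89, permutation p = 0.647) or without replicate 2 (4.57, p = 0.0535), and it was 41.1 in the strongest 1710 peaks (permutation p = 1e-05).

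Summits were spread over all arms, with a surplus on arm 2L and a deficit on chromosome 4. Arm 2L held 690 summits (20.2%, with 17.6% of the sequence; exact binomial test with Benjamini-Hochberg adjustment over 6 arms, adjusted p = 3.1e-04). Chromosome 4 held 10 (0.292%, with 0.996% of the sequence; exact binomial test, adjusted p = 1.5e-05). The X chromosome held 567 summits, 2R held 633, 3L held 734 and 3R held 787, none past the threshold. Against the shares of the 30000 pooled peaks, neither 2L (18.5%, exact binomial test, adjusted p = 0.0932) nor chromosome 4 (0.357%, adjusted p = 0.961) passed. Arm 2L did not pass in the strongest 1710 peaks either (19.6%, exact binomial test, adjusted p = 0.0851).

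Of 13945 protein-coding genes, 2983 (21.4%) had at least 1 thresholded summit between 2 kb upstream of the gene and its end, and are called bound here. The genes with the most summits were sbb and CG1677 with 12 each, and ush, Eip75B and kirre with 11 each. sbb encodes a nuclear zinc-finger protein and its strongest peak had a signal of 1077. Eip75B encodes an ecdysone-induced nuclear receptor and its strongest peak, 32 bp downstream of a TSS, had a signal of 305. ush encodes a cofactor of GATA factors. The strongest peaks in the windows of CG1677 and kirre lay at the TSS of other genes inside those windows, CBP (signal 909) and Syx4 (signal 524).

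Genes for cytosolic ribosomal proteins were bound far more often than genes with windows of similar length. Of the 92 members, 67 were bound, against a mean of 13.2 ± 3.28 (SD) in 10000 random lists matched on window length (two-sided permutation p = 2e-04, the smallest these lists can give; adjusted p = 0.004 over 20 lists). The strongest were RpL7 (signal 538, summit 35 bp upstream of the TSS), RpL30 (532, 9 bp upstream) and RpS27 (496, 4 bp upstream). RpL34b was counted through a peak of signal 516 (arm 3R, 9401275 to 9401526) just upstream of its own start at 9401226. The nearest TSS was that of the neighbouring CG8132, 90 bp from the summit. The 67 genes shared 66 strongest summits, of which 63 lay within 500 bp of a TSS. Their median signal was 273, against 214 for all summits at a TSS. RpL5 was among the 25 members without a summit. This was the only list of the 20 past the threshold, and no list was bound less often than matched lists after adjustment.

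Genes of the EGFR pathway and of oenocytes had the highest bound share, 10 of 13 against 5.64 ± 1.76 in matched lists (p = 0.0262, adjusted permutation p = 0.215). The strongest peaks lay in an intron of aos, a secreted inhibitor of the EGF receptor (signal 658), in an intron of S (545), 1494 bp upstream of aop, which encodes an Ets-family repressor (525), and 276 bp upstream of the nuclear receptor gene Hnf4 (355). aop held 6 summits. No summit lay in the windows of svp or kek1. This list passed when each summit was given to a single gene (adjusted permutation p = 0.05, just below the threshold before rounding), and in none of the other 7 alternatives, where adjusted permutation p ranged from 0.173 to 1 and the count fell to 3 (against 2.45, within 1 kb of the TSS).

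Gut regulators had 7 of 11 members bound (3.86 expected from matched lists, adjusted permutation p = 0.346), led by bowl with 4 summits (579), then otp (296), bin (258) and fkh (251), and without peb or drm. The summit counted for otp lay in coding sequence, and the nearest TSS was that of Cib2, 4662 bp away. Cell cycle genes had 8 of 16 bound (3.85 expected, p = 0.0418, adjusted permutation p = 0.215), with CycE at 349 and Dp at 336. The count was 6 without replicate 2, and 4 against 2.66 with each summit given to a single gene (adjusted permutation p = 0.865). The peaks counted for Dref and PCNA lay 3 bp upstream of the TSS of RpL13 and 19 bp downstream of that of RpS18. The peak counted for Dref (arm 2L, 9967250 to 9967397) also lay just upstream of the start of Dref at 9967229. CycA and stg had none. Among heat shock genes 5 of 14 were bound (2.39 expected, adjusted permutation p = 0.411), with Hsp27 at 832, Hsp83 at 493, Hsp26 at 396 and Hsp22 at 174 (no summit without replicate 1). The peak counted for Hsp22 lay in a 5′ untranslated region, 510 bp from the nearest TSS, that of CG4456. The same peak counted for another member of the list. Hsp70Aa and Hsp70Bc had no summit, but the Hsp70 genes are duplicated copies where reads are hard to place uniquely, so this is uncertain.

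The lists for the tracheal system, sensory organs and the embryonic head, where Salm is known to act, did not pass. Tracheal genes had 7 of 15 bound (5.64 expected, adjusted permutation p = 0.823), among them the FGF gene bnl (signal 492), the tracheal master regulator trh (417, summit 364 bp upstream of the TSS), rib (310) and pnt (6 summits, 274), while uif and knrl had none. Sensory organ genes had 3 of 15 bound (4.42 expected, adjusted permutation p = 0.823): N at 487, neur at 405 and ct at 198, with none at pros or, except without replicate 2, at ham. Gap and head gap genes had 2 of 17 bound (5.27 expected, adjusted permutation p = 0.384), cnc at 275 and so at 152, with none at ey; without replicate 2 only 1 was bound, and so had no summit. Homeotic genes and cofactors had 4 of 12 (5.16 expected, adjusted permutation p = 0.823), with 6 summits each at Antp (329) and hth (288), then Abd-B (235) and lab (214), and none at Ubx or pb; without replicate 1, hth had 3 summits and lab 0. Dpp pathway genes and wing targets had 8 of 18 (6.64 expected, adjusted permutation p = 0.823), with Dad at 552, Mad at 504, tkv at 458 and brk at 391, and none at mirr.

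Of the segmentation genes, the segment polarity list had 6 of 14 members bound (5.38 expected, adjusted permutation p = 0.989), with fz at 493, ptc at 470, nkd at 324 and H15 at 216, and none at inv or hh. In the pair-rule list only hry was bound (187, summit 95 bp upstream of the TSS; 1 of 11 against 2.58, adjusted permutation p = 0.823), with none at opa. Neuroblast genes had 6 of 17 (5.37 expected, adjusted permutation p = 0.989), with elav at 800 (summit 249 bp upstream of the TSS), the midline regulator sim at 596, grh at 414 and nub at 230, and none at pdm2 or Dr. Glial genes had 4 of 8 (2.5 expected, adjusted permutation p = 0.823), with moody at 507, loco at 181 and Gli at 178, and none at gcm2 or, except without replicate 2, at nrv2.

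Muscle genes had 7 of 20 bound (7.28 expected, adjusted permutation p = 1). The strongest peak counted for Mef2 (1223, rank 36) lay 169 bp upstream of the TSS of Pal1 inside the Mef2 window. The heart and muscle regulator tin had 1 summit 243 bp upstream of its TSS (496), and sls had 1 of signal 351, while twi and sns had none. Fibrillar flight muscle genes had 2 of 9 (3.38 expected, adjusted permutation p = 0.823), sls and Tm1 (174), with none at bru1 or Strn-Mlck. Of this list 3 members were bound without replicate 1 and 1 without replicate 2, where Tm1 had no summit. Photoreceptor genes had 3 of 16 (4.27 expected, adjusted permutation p = 0.823), norpA at 623, Rh5 at 464 and ninaE at 213, with none at sev or trpl.

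Hemocyte and fat body genes had the lowest bound share, 1 of 14 against 4.76 ± 1.71 (p = 0.043, adjusted permutation p = 0.215): only ush was bound, and Pxn and lz had none. In the germline list ovo was bound (216; 1 of 10 against 2.82, adjusted permutation p = 0.823; 2 without replicate 1), with none at vas or tud. Cuticle and epidermal genes had 4 of 16 (5.91 expected, adjusted permutation p = 0.823), with sn at 348, nyo at 169 and tyn at 144 (no summit when either replicate was left out), and none at f or m. Of the 2 members of the spalt list, too short to test, salm was bound.

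**Figure D4:**
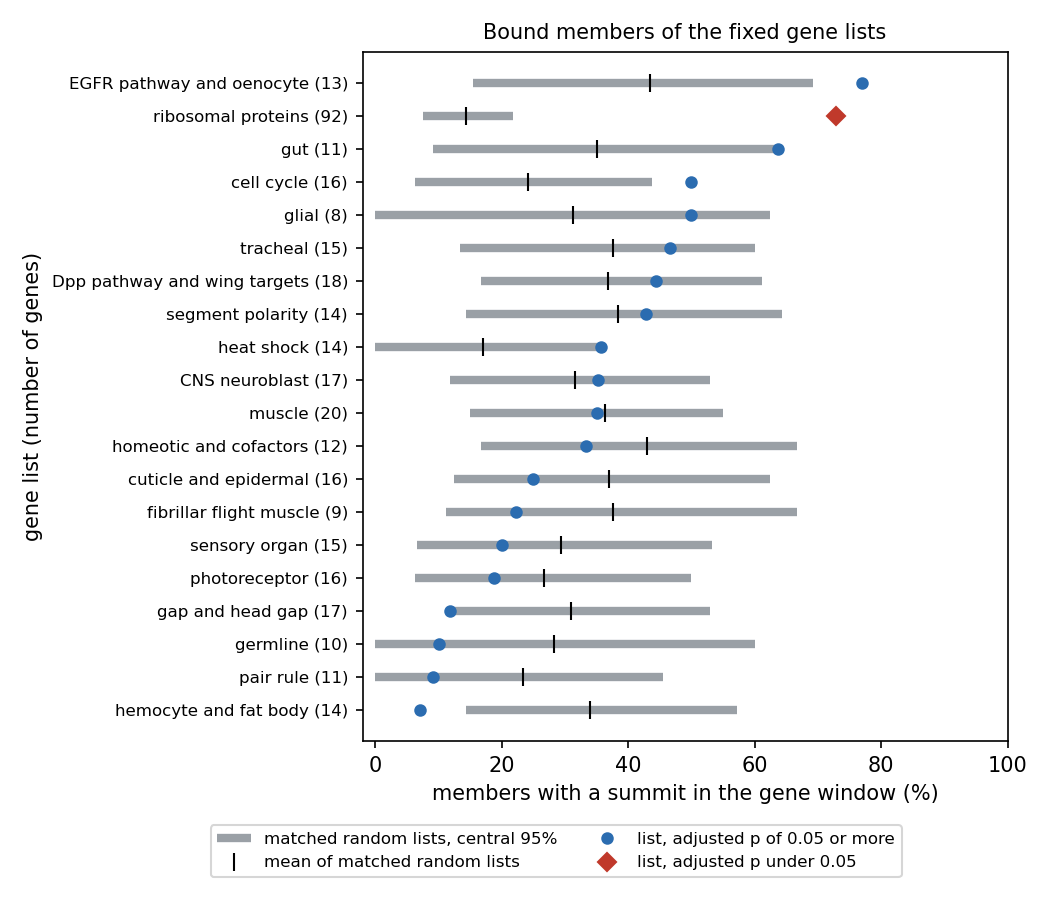
Percent of each fixed list's members with a thresholded summit in the gene window (points, red where the adjusted p is under 0.05) against matched random lists (grey bars, central 95%; black ticks, mean), with the number of genes in parentheses. Ribosomal protein genes lie at 72.8%, outside the range of their matched lists.

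The bound sites were rich in A and T. The mean GC content within 50 bp of the summit was 33.4% ± 9.49 (SD over peaks), against 43.3% ± 9.93 in windows of equal width 300 bp to a side, and it was lower at the summit for 2538 of the 3421 peaks (two-sided sign-flip permutation test with 100000 resamples, p = 1e-05, the smallest they can give). From the strongest to the weakest quintile of peaks, the mean GC content was 29.6, 32.3, 33.5, 35.0 and 36.7%. The A/T-only word AATATT, known as a sequence bound by vertebrate SALL proteins, lay within 50 bp of 659 summits (19.3%) and in 247 flanks (7.22%; exact McNemar test with Benjamini-Hochberg adjustment over 12 motifs, adjusted p = 5.5e-47). Its share was 24.5% in the strongest quintile (interval 21.3 to 27.9) and 13.7% in the weakest (11.3 to 16.6). In 61.4% of the thresholded peaks the summit was the middle of the peak. Whether this share varied with signal was not tested. The trends of GC content and AATATT over quintiles therefore cannot be tied to binding strength alone.

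**Figure D5:**
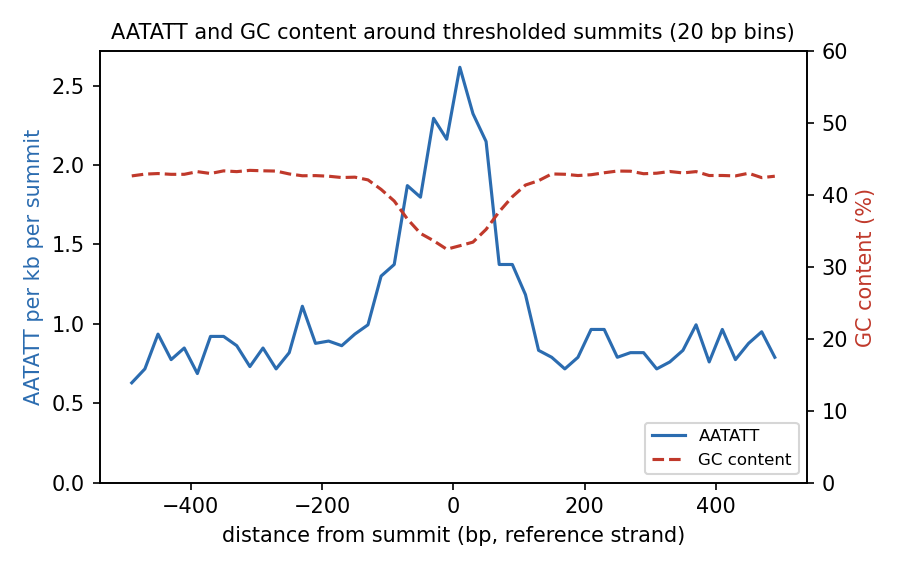
Number of AATATT per kb and summit (blue, left axis) and GC content in percent (red dashes, right axis) in 20 bp bins around the 3421 thresholded summits, by distance in bp. AATATT is most frequent, at 2.62 per kb, in the bin centred 10 bp from the summit, where the GC content is 33.0%.

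Of the 12 fixed motifs, 5 were more frequent at summits and 2 less frequent. The homeodomain core TAATTA lay at 345 summits and 192 flanks (exact McNemar test, adjusted p = 3.4e-11), the GATA motif AGATAA at 327 and 190 (adjusted p = 1.4e-09), the E-box CATATG at 148 and 92 (adjusted p = 4.7e-04) and the core promoter element Motif 1, GGTCACAC, at 31 and 8 (adjusted p = 5e-04). The GAGA element was less frequent at summits, with GAGAGA at 134 against 218 flanks (exact McNemar test, adjusted p = 1.4e-05), as was CAAGTG, bound by NK homeodomain proteins, at 162 against 265 (adjusted p = 8.5e-07). The other motifs did not pass: TATCGATA, the DNA replication-related element, at 33 and 18 (exact McNemar test, adjusted p = 0.0652), TACGTG at 60 and 85 (adjusted p = 0.0599), CAGGTAG at 16 and 24 (adjusted p = 0.293), ATGCAAAT at 64 and 52 (adjusted p = 0.303) and TGGGAA at 167 and 195 (adjusted p = 0.177). Against shuffled summit sequences with unchanged dinucleotide counts, TAATTA was less frequent than in shuffles (ratio 0.79) and GAGAGA more frequent (ratio 1.79), while AATATT stayed higher (ratio 1.39). Several of these calls depended on the comparison. TATCGATA passed in 5 of its 6 alternatives, with ratios from 2.39 to 5.71 over all of them (3.9 without replicate 1 and 3.36 without replicate 2). TACGTG passed as less frequent with windows of 100 bp (exact McNemar adjusted p = 0.00451) and against shuffles (permutation adjusted p = 0.0297), and CAGGTAG with windows of 100 bp (exact McNemar adjusted p = 0.0188). ATGCAAAT passed as more frequent without replicate 1 (exact McNemar adjusted p = 0.0109). TGGGAA passed as less frequent without replicate 2 (exact McNemar adjusted p = 0.0122) and with flanks at 1000 bp (adjusted p = 0.0477), and as more frequent against shuffles (permutation adjusted p = 0.0297). CATATG did not pass in the strongest 1710 peaks (ratio 1.36, exact McNemar adjusted p = 0.124), without replicate 2 (1.20, adjusted p = 0.201) or with flanks at 1000 bp (1.20, adjusted p = 0.183). GAGAGA did not pass with windows of 100 bp (0.888, exact McNemar adjusted p = 0.0892) or flanks at 1000 bp (0.876, adjusted p = 0.293), AGATAA against shuffles (1.04, permutation adjusted p = 0.416), CAAGTG against shuffles, where its direction turned (1.26, permutation adjusted p = 0.0528), or GGTCACAC in the strongest 1710 peaks, where fewer windows held it (exact McNemar adjusted p = 0.0781). The ratio of GGTCACAC, 3.88, was 8 in the strongest 1710 peaks, 9 without replicate 1 and 2.73 without replicate 2, so its size depends on the peaks used.

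Without a preset motif, 384 of 2080 words of 6 bases were more frequent at summits than in flanks, and 915 were less frequent. All 36 words made only of A and T were among the 384. The first by p was AAATAT, at 1221 summits and 533 flanks (exact McNemar test, adjusted p = 6.1e-74), followed by TAAATA at 1107 and 506, ATTTAA at 975 and 432 and AATATA at 822 and 336. Among the less frequent words, CTCCTC lay at 38 summits and 172 flanks (exact McNemar test, adjusted p = 9.9e-21) and GCGGCA at 69 and 230 (adjusted p = 2e-20).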

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

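The dinucleotide shuffles, the assignment of each summit to a single gene, the GC-matched positions and the removal of neighbouring summits were chosen after the results were seen, and the other alternatives before. Of 58 values under an alternative of the main results, 45 kept direction and side of the threshold, where counts were judged by size alone, so the classes or motifs counted can differ. The replicate overlap of 74.4% became 61.6% with 50% reciprocal overlap, 70.3% for summits within 100 bp, 79.3% with the strongest 1710 peaks and 70.6% with all peaks. Thresholded summits in both replicates (98.8%) fell to 95.7% for a summit within 100 bp and 72.6% in the strongest peaks, and rho was 0.793 in the strongest 1710 peaks. The arms past the threshold went from 2 to 1 with the strongest 1710 peaks and 0 against pooled peaks. Lists with more bound genes went from 1 to 2 with a single gene per summit, and enriched fixed motifs from 5 to 3 with the strongest 1710 peaks. The signal difference of 13.9 was 41.1 in the strongest 1710 peaks, 1.89 with a 250 bp TSS window, and 4.57 and 4.88 without a replicate, on the scale of the other replicate's list. The promoter share stayed between 36.5 and 57.7% and passed in all of its alternatives, and the GC difference stayed between -12.4 and -7.59 points. Ribosomal protein genes passed in all 8 list alternatives, with 51 to 76 bound. Directions turned against matched lists, with no pass, as follows. With the nearest TSS, bound genes were gap 6, pair-rule 4 and muscle 8. With 10 kb on either side they were segment polarity 8, tracheal 9, hemocyte 9, germline 7 and cuticle 10. Matched on a pooled peak they were segment polarity 6, tracheal 7, neuroblast 6 and photoreceptor 3. Within 1 kb of the TSS they were neuroblast 3, Dpp 3 and gut 2. With the strongest 1710 peaks they were homeotic 4, muscle 7 and photoreceptor 3, without replicate 1 neuroblast 5 and muscle 8, and with a single gene per summit muscle 7. Arm 3L turned to 20.9% in the strongest 1710 peaks and 21.5% against pooled peaks (22.5%), X to 18.0% in the strongest 1710 peaks, and 5′ untranslated regions stayed at 0.672% against a GC-matched 0.581%. CAGGTAG turned to a ratio of 2.20 in the strongest 1710 peaks. Against shuffles CAGGTAG had 1.30, GAGAGA 1.79, CAAGTG 1.26, TGGGAA 1.40 and TAATTA 0.79. Except where fewer peaks were used, the cause was not tested. No paired analysis was possible because there is 1 group. The read depth is unknown, so a gene without a summit is only below the threshold at that depth.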

Other observations

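Apart from the matching of lists on pooled peaks, the tests in this part were chosen after the main results were seen, and those of AATATT against shuffles and of weak peaks around salm against all genes were set after these values were known. Protein-coding genes were grouped by the letters of their symbols before the number, and the 93 groups of at least 8 genes were compared with 10000 lists matched on window length. The only groups bound more often than matched lists were the ribosomal protein groups RpL (37 of 50 against 7.20) and RpS (27 of 38 against 5.47), each with an adjusted permutation p of 0.00465. Chemosensory receptor genes were bound less often: 0 of 60 ionotropic receptor genes (Ir, against 11.4), 1 of 60 gustatory receptor genes (Gr, against 9.94) and 2 of 59 odorant receptor genes (Or, against 9.71), with adjusted permutation p of 0.00465, 0.0093 and 0.0372. The same held for cytochrome P450 genes (Cyp, 3 of 85 against 16.5), cuticular protein genes (Cpr, 1 of 70 against 10.3), the neuronal surface proteins of the dpr group (2 of 21 against 8.93) and histone genes (His, 1 of 115 against 8.39), with adjusted permutation p of 0.00465, 0.00744, 0.0209 and 0.0209. Most histone genes are near-identical copies in a tandem array, where reads are hard to place uniquely, so their value is uncertain.

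Outside protein-coding genes, 39 of 290 tRNA genes (13.4%, exact 95% interval 9.74 to 17.9) had a thresholded summit within 500 bp of a TSS, as had 1879 of 13945 protein-coding genes (13.5%). A gene counted when any of its TSSs had a summit near, so genes with more TSSs had more chances and the shares are not directly comparable. Neighbouring genes could also share a summit, which the interval does not cover. The shares were 18 of 269 for snoRNA genes (6.69%) and 161 of 3261 for other non-coding RNA genes (4.94%), and of 99 rRNA genes 0 had a summit, although most of these too are repeated copies where reads are hard to place. Summits at promoters and far from them also differed in sequence. AATATT lay at 17.1% of the 1605 summits within 500 bp of a TSS and at 23.1% of the 1023 summits over 2 kb away (Fisher's exact test, adjusted p = 2.8e-04 over 4 words), although their mean GC content was 33.8% and 33.2%. The promoter words TATCGATA (30 against 3 summits, Fisher's exact test, adjusted p = 2.8e-04) and GGTCACAC (29 against 1, adjusted p = 4.7e-05) lay nearly all at promoter summits. GAGAGA lay at 3.61% and 3.62% (Fisher's exact test, adjusted p = 1). In the flanks of the same summits TATCGATA lay at 15 against 2 and GGTCACAC at 7 against 1. These tests therefore do not separate the bound sites from promoter sequence in general.

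The binding of 67 of 92 ribosomal protein genes was weighed first. It was not accounted for by having a pooled peak in the gene window: against lists matched also on this, 67 remained above a mean of 22.5 (permutation p = 2e-04, the smallest these lists can give). The match took a pooled peak anywhere in the window, thresholded or not. It cannot decide whether a weak signal at promoters in particular accounts for the excess. Whether the excess goes with the AT-rich word was tested on the 66 strongest ribosomal protein gene summits. AATATT lay at 10.6% of them and at 12.1% of their flanks (exact McNemar p = 1). A share at or below that of the flanks had been set to count against this explanation. The result met that rule, but with 7 summits against 8 flanks it is too few windows to decide. TATCGATA lay at 8 of these summits and at 0 flanks (exact McNemar p = 0.0078). Another list held 22 genes taken to be highly transcribed, for translation factors, the cytoskeleton and metabolism among others. It had 13 bound members against 4.68 (permutation p = 8e-04). Without Gapdh2, whose peak was already known, 12 of 21 were bound. The genes were chosen without expression values from these embryos. A strongest peak of signal 212 was shared by some bound members and counted for each. A raised ChIP signal over any strongly transcribed promoter may therefore account for this pattern, and no control precipitation without the tag was analysed here and no biological explanation was tested.

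The AT-rich words at summits were weighed next. Core promoters alone do not account for AATATT, which lay at 23.1% of summits over 2 kb from any TSS and at 6.74% of their flanks (exact McNemar p = 5.9e-25). The other enriched words were not tested in this way. For the 384 enriched words as a set, base composition is a candidate explanation: the median ratio to dinucleotide shuffles of the same windows was 0.966, against 0.994 to 1.00 for 20 other shuffles. AATATT itself, fixed beforehand, lay in 659 windows, 1.39 times the mean of 100 shuffles and above the highest of them, 511. The dinucleotide composition of these windows thus does not account for its number there. Some words less frequent at summits than in flanks also exceeded 30 shuffles, such as CAGCTG (ratio 2.52) and AGAGAG (2.05). The flanks were not shuffled, so whether composition accounts for the difference of AATATT between summits and flanks is not decided. Of 36 A/T-only words 16 lay above 1 against 30 shuffles (median 0.986), with ATATAT (1.56) and AAATAT (1.49) above AATATT and TAAATA (1.38 each), and no biological explanation was tested.

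The peaks around salm were weighed last. The salm window of 111304 bp held 8 thresholded summits, and 88.8% of equally wide windows around 13944 other protein-coding genes held fewer. An unusual cluster of thresholded summits is thus not established. The salm window also held 52 weak pooled peaks, against a median of 25, and 96.0% of the other windows held fewer. Extra copies of the salm region in the tagged line may raise the background there. Around 53 gap, pair-rule, segment polarity and homeotic genes the median was 29 weak peaks, and 92.5% of these windows held fewer than the salm window. As a set these regulators were thus only slightly denser than other genes, but some of their windows held as many weak peaks as salm or more. A high density of weak peaks around some developmental regulators therefore stays open as well. Binding of Salm to its own gene was not tested apart from these.

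Among hypotheses on gene groups, Eip75B with its 11 summits led to a list of 18 other ecdysone response genes, of which 8 were bound against 6.98 in matched lists (permutation p = 0.775), which decides nothing. The strong peaks at mRpS10 and mRpL41 led to the other 71 mitochondrial ribosomal protein genes, of which 16 were bound against 8.38 (permutation p = 0.013; adjusted p = 0.0173 over the 4 lists formed after the results were seen, 2 of which differ only by Gapdh2). Of these 16, 1 was counted through the already seen strong peak at the TSS of CenG1A; without it 15 of 70 were bound against 8.22 (permutation p = 0.031, unadjusted). In the scan of 93 symbol groups neither mRpL (11 of 47 against 5.31, adjusted permutation p = 0.16) nor mRpS (7 of 26 against 3.22, adjusted permutation p = 0.301) passed; that scan adjusted over more lists, split the group and included mRpS10 and mRpL41, so whether this group is bound more often stays open.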
